A study of Mus musculus with 9 samples.

How the data were processed

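The series holds 9 arrays of mouse ES cells, biotin-labelled from total RNA, with 1 array for undifferentiated cells and 1 for each of 4 days of differentiation in each of 2 media, with or without doxycycline. Groups were taken from the labels. The labels' protocols state that ES cells were maintained with leukemia inhibitory factor and doxycycline and differentiated in medium with serum and no such factor. No replicate of any group was analysed here, so the 4 days stand in for repeats of the comparison of media, and the 2 media for repeats of the comparison of days. P-values then measure only the spread between these arrays.

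The authors deposited 1 table of intensity values per probe set, on a linear scale. Per the submitters' processing notes, the signals were made with GCOS, Affymetrix's array software; its version, the background correction and any detection filter are not given in the sources used here. The labels name a scaling to an average of 100, and the deposited intensity values bear this out: the mean of 45101 probe sets without the highest and lowest 2% was 100 on every array. No scanner files were used here. No genome was used here, so no coordinates are given, and gene names come from the platform annotation, updated through gene IDs with the RefSeq gene table of assembly GRCm38.p6.

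Of the 45101 probe sets, 34945 have 1 gene symbol, 932 have several and 9224 are unnamed here, and 34741 symbols were matched through the gene ID. The 64 control probe sets are included in these numbers, but not among those with 1 symbol. Probe sets with several symbols were left out. Each of the 18193 genes was represented by its brightest probe set with 1 symbol over all 9 arrays; 9010 genes had more than 1. Among genes named under the rule given below, and among those of the fit of D2.5 and D3.5, other probe sets were checked in the comparison each gene was named for. One of Wwc1 went the other way by at least 0.5 on the log2 scale (0.61 against -0.90 on D0.5), and no other did; smaller values of the other sign, as for dim probe sets of Gata6 and Utf1, were not counted. Some listed genes had no such probe set and were not analysed here, among them T (brachyury), H19 and Ccnb1. Because the arrays already shared 1 scale, no further normalization was applied. Values are log2(signal + 16), and 8716 genes with a signal of at least 50 on at least 2 of the 9 arrays were tested.

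For the comparison of media, limma (version 3.58.1, in R 4.3.3) was fitted to the 8 differentiating arrays with the day as a block (lmFit, then eBayes with a mean-variance trend; 3 residual degrees of freedom), and days were compared in the same fit with the medium as a block. A steady change of the medium's effect was tested as the product of medium and day (4 residual degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Single days, and undifferentiated cells against each array, were described by counts of genes at least 2-fold apart, without a test. Gene lists were tested with camera at a preset correlation of 0.01, for the 24 of 26 lists with at least 5 tested genes; the Hox genes and the genes of the two-cell-like state had 0 tested members. Percentiles of list medians are among 10000 random lists of equal size, matched in 20 bins of mean expression.

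Lists, tests, filters and alternatives were fixed before the data were examined, except where the text says otherwise. Named genes follow a rule fixed at the same time. For the comparison of media these are the 10 genes furthest up and down with a steady sign on all 4 days, the 3 largest members of each list, and a set always given (Prkaca, Pou5f1, Sox2, Nanog, Zfp42, Fgf5, Dnmt3b, Ehmt2, Mixl1, Kdr, Pdgfra, Gata6 and Sox17). For each single day they are the 5 furthest up and down, for the days the 10 furthest up and down among called genes and the 3 largest members of each list, for undifferentiated cells the 5 furthest each way, and for the change with day the 3 with the smallest p. Other genes named as examples of a list were chosen after their values were seen.

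A further fit was added after the values were seen. It tests 1 difference of media shared by D2.5 and D3.5, with the day as a block and the pairs of D0.5 and D1.5 contributing only to the spread (3 residual degrees of freedom), and its genes were named after their values were seen. Because it was chosen from the same values, its p-values are a description of these arrays.

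The fits and list tests were tested on simulated data made with the residual spread of the real fits, with 50 of 8716 genes changed at each size. A change of 1 on the log2 scale was recovered for 76% of genes in the comparison of media, 64% in that of days, 84% in the change with day and 70% in the fit of D2.5 and D3.5, with 12, 6, 17 and 12 false calls. Changes of 2 were recovered for 98%, 98%, 98% and 100%. The changed genes were drawn at random, and their change had exactly the form that each fit assumes, such as the same size on every day. Real differences between the media varied from day to day, so these rates do not carry over to them. Igf2, at 3.19 ± 0.72 between the media, was not called. A list of 15 genes moved by 1 was called in 100% of 50 draws, with 1 false call among 1150 unmoved lists. These lists were random genes with independent errors. The real lists had estimated correlations between genes of up to 0.77 (lateral plate and heart genes), so this rate of false calls does not carry over to them.

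The alternatives were quantile normalization of the log2 values, centring each array on its median, pseudocounts of 1 and 64, no filter on dim genes or a filter at 100, the mean of all probe sets of a gene, eBayes without trend, fits without the day or the medium as a block, an estimated correlation in camera, and leaving out each day or each array of D0.5 and D3.5 in turn. The day pairs the media because the labels put 1 array of each medium on each day, and the fit with the day as a block is the one reported. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.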

Results

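Gene expression was measured in mouse embryonic stem (ES) cells on 9 arrays: 1 of undifferentiated cells and 8 of cells taken 0.5, 1.5, 2.5 and 3.5 days after the start of differentiation (D0.5 to D3.5), with (Dox+) or without (Dox-) doxycycline at 1 µg/ml. Per the labels, doxycycline controls a constitutively active form of protein kinase A (PKA), the kinase that cyclic AMP activates, and the comparison asks how PKA activity bears on early differentiation. The labels do not state which medium switched the kinase on, so the arms are named by their medium. Each combination of day and medium is 1 array with no replicate, and the number of arrays limits the precision of every value. Between 41.6% and 44.2% of genes had a signal of at least 50 per array. The ratio of 3' to 5' signal of Actb, a sign of RNA integrity, lay between 1.60 and 1.98, with 1.94 on the Dox+ and 1.63 on the Dox- array of D3.5. Values are array signals scaled to a mean of 100, and differences are on the log2(signal + 16) scale, which understates the change of dim genes.

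Prkaca, which encodes the catalytic subunit of PKA, did not part the arms. Its signal was 511 in undifferentiated cells, 467, 544, 538 and 618 on the Dox+ arrays of D0.5 to D3.5, and 555, 508, 611 and 390.2 on the Dox- arrays. The fitted Dox- minus Dox+ difference was -0.08 ± 0.16 (SE, 4 days; limma adjusted p = 0.844). A second, dimmer probe set of the gene gave -0.04. Whether these probes detect the introduced form of the kinase is not given in the sources used here, so this signal does not check the labels. Of the 11 tested genes for PKA subunits, inhibitors and anchoring proteins, 0 passed over all genes and 2 passed adjusted over the list alone. These were Pkig, a PKA inhibitor (0.49 ± 0.10, higher in Dox- on 4 of 4 days), and Prkar1a, a regulatory subunit (0.39 ± 0.10). The next brightest probe set gave only 0.12 for Pkig, and 0.38 for Prkar1a. The list as a whole did not pass (camera adjusted p = 0.319), and its median of -0.01 differed in sign from its mean of 0.05. Neither did the 14 tested cyclic AMP-responsive genes (adjusted p = 0.152, with 0 members past adjusted over the list alone), whose median difference was highest on D1.5, at 0.40.

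Genes of vascular and blood precursors were higher in Dox- cells from D1.5 on. On D1.5, 9 of the 10 tested genes of this list were at least 2-fold higher in Dox-, and their median difference was 2.05, against 0.08 on D0.5. The signal filter left out 14 of the 24 genes on the list. Over all 24 the median on D1.5 was 1.17, with 14 genes at least 2-fold higher and 0 at least 2-fold lower in Dox-. Etv2, a regulator that specifies endothelial and blood progenitors, read 408 in Dox- and 25.1 in Dox+ on D1.5. Kdr, the main receptor of vascular endothelial growth factor, read 87.4 against 8.7 on D1.5 and 483 against 21.1 on D3.5. Etv2, Fli1, Ctla2a, Igf2 and the apelin receptor gene Aplnr had the 5 largest differences upward on D1.5. These single-day values compare single arrays and carry no test.

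Primitive streak genes were higher in Dox- on D2.5, and genes of lateral plate and heart mesoderm on D2.5 and D3.5. All 12 tested streak genes were at least 2-fold higher in Dox- on D2.5, with a median difference of 4.31, which was 0.77 on D3.5. On D1.5 their median was already 0.87, with 5 at least 2-fold higher and 0 lower, but 0.22 over all 23 genes with a probe set. Over all 23 streak genes, dim ones included, the D2.5 median was 2.80, with 19 at least 2-fold higher and 0 lower. Mixl1 and Mesp1, transcription factor genes of the streak and of nascent mesoderm, read 1177 against 15.7 and 1432 against 14.6 on D2.5. Mixl1 then read 465 in Dox- and 302 in Dox+ on D3.5. The 9 tested lateral plate and heart genes had a median difference of -0.08 on D1.5, 1.94 on D2.5 and 3.5 on D3.5. Over all 20 genes of the list the median was 0.96 on D2.5, with 9 at least 2-fold higher and 0 lower, and 2.73 on D3.5. The cardiac regulator genes Tbx20 and Isl1 read 855 against 8.2 and 506 against 13.1 on D3.5. The 9 tested definitive endoderm genes had a median of 1.48 on D2.5 and -0.98 on D3.5, and all 16 genes of the list 0.91 and 0.03. No Hox gene passed the signal filter. Over all 22 Hox genes with a probe set the median was 0.09 on D2.5 and 1.32 on D3.5. On D3.5, 12 of them were at least 2-fold higher in Dox- and 0 lower.

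Naive pluripotency genes were lower in Dox- on D1.5, and primed epiblast genes on D3.5. The 18 tested naive genes had a median difference of -1.10 on D1.5, with 10 at least 2-fold lower and 0 at least 2-fold higher, and of -0.04 on D2.5. On D3.5 the median was 0.31, with 3 genes at least 2-fold higher in Dox-, among them Tbx3 at 1061 against 58.6, and 3 at least 2-fold lower. Zfp42 (Rex1), a marker of naive cells, read 136 against 323 on D1.5, and Klf2 read 16.9 against 171. The 20 primed epiblast genes had a median of 0.26 on D1.5 and -1.46 on D3.5, where 13 were at least 2-fold lower. Fgf5, a marker of the primed epiblast, read 755 in Dox- and 419.6 in Dox+ on D1.5, but 21.0 and 708 on D3.5. Pou5f1 (Oct4) read 2614, 2095, 1735 and 524 on the Dox- arrays of D0.5 to D3.5 and 2724, 2223, 2043 and 2099 on the Dox+ arrays. Nanog read 1324 in Dox- and 826.3 in Dox+ on D2.5, and 306 and 1887 on D3.5.

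Across all 8716 tested genes, 10 were at least 2-fold apart on D0.5, 240 on D1.5, 685 on D2.5 and 778 on D3.5. These counts depended on the pseudocount, with 77 on D0.5 and 425 on D1.5 at a pseudocount of 1, and 1, 82, 343 and 414 on the 4 days at a pseudocount of 64. The D0.5 genes included Rad21, a cohesin subunit, at 1943 in Dox- and 844 in Dox+, and Ttpa at 139 and 316. The D1.5 arrays also held Adm, Klf2, Dmrt1, Fbxo15 and Mymx as the 5 genes furthest down in Dox-, and the D3.5 arrays Eras, Pim2, Fgf5, Slc27a2 and Otx2. Differences of D2.5 and D3.5 correlated across genes at a Pearson's r of 0.557 (Spearman's rho 0.470), the highest of the 6 pairs of days, and those of D1.5 and D3.5 at 0.0920 (rho 0.0970). Genes are not independent replicates, so these coefficients carry no p.

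**Figure D1:**
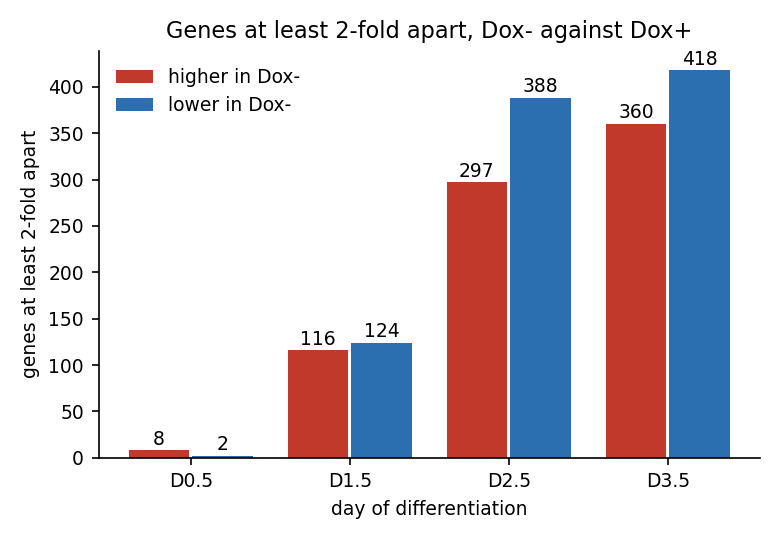
Number of the 8716 tested genes (vertical axis) at least 2-fold higher or lower on the Dox- array than on the Dox+ array of each day (horizontal axis). The totals are 10, 240, 685 and 778 genes, with 1 array per medium and day.

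**Figure D2:**
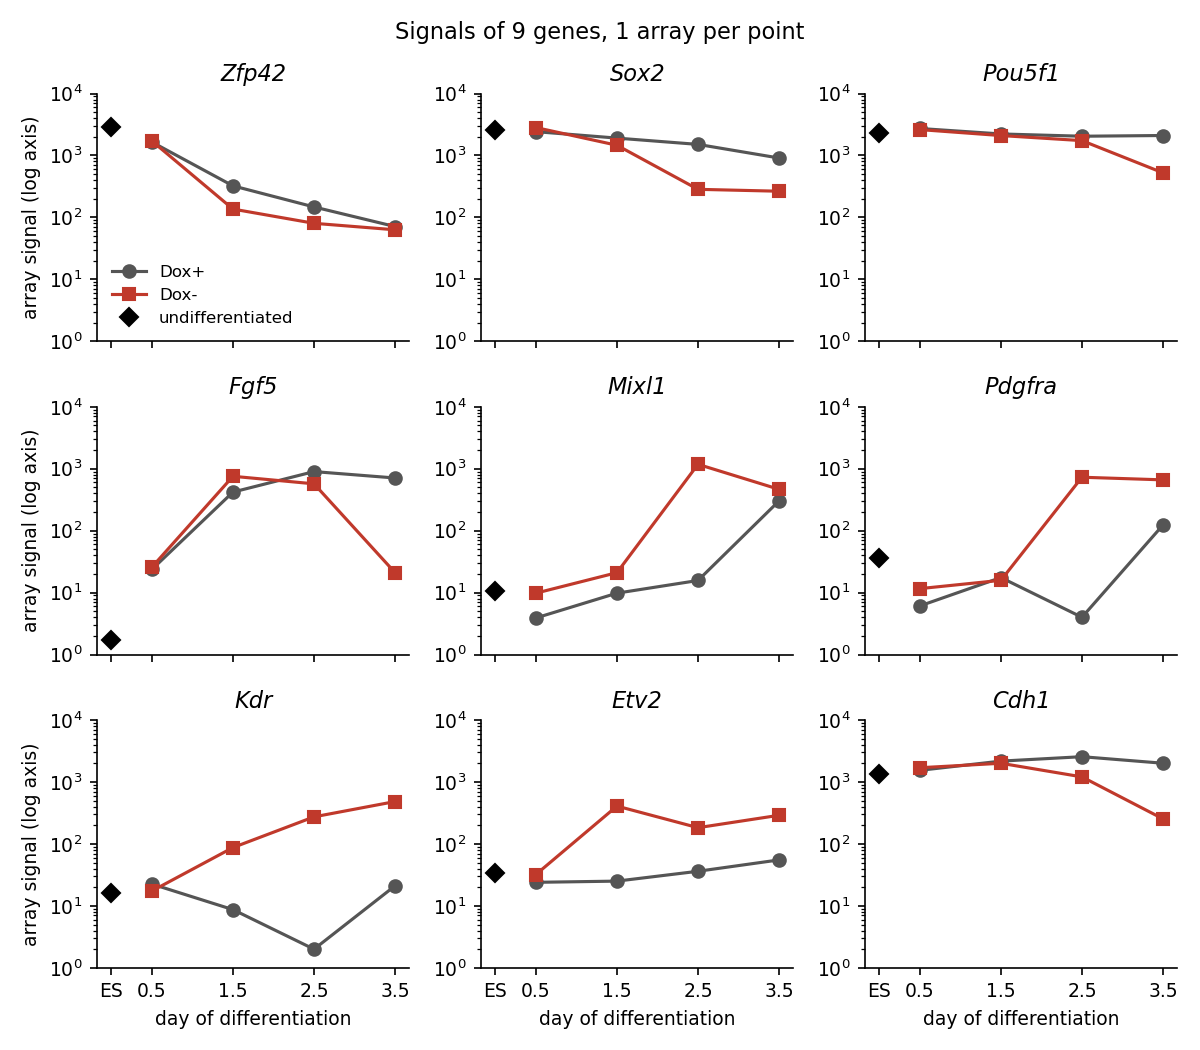
Array signal on a log axis against the day of differentiation for 9 genes, with Dox+ arrays as circles, Dox- arrays as squares and undifferentiated cells (ES) as a diamond, 1 array per point. Etv2 and Kdr are higher in Dox- from D1.5 and Mixl1 and Pdgfra from D2.5, while Sox2 is lower from D2.5, and Fgf5 and Cdh1 are lower on the D3.5 Dox- array than on the Dox+ array of that day.

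Over the 4 days together, 7 gene lists lay higher in Dox- and 4 lower, while no single gene passed. The higher lists were vascular and blood precursors (camera adjusted p = 1.17e-07), primitive streak (3.51e-05), lateral plate and heart mesoderm (0.000244), extraembryonic endoderm (0.00181), trophoblast (0.0022), targets of Wnt, Nodal, BMP and FGF signals (0.0123), and cytoskeleton and epithelial-mesenchymal genes (0.0285). The lower lists were germline genes (0.00181), general pluripotency (0.0075), chromatin and DNA methylation enzymes (0.0123), and glycolysis and hypoxia (0.0343). All 11 calls were lost when the correlation between genes was estimated from the data, with adjusted p = 0.529 with an estimated correlation for 10 lists and 0.651 for glycolysis and hypoxia. A fit without the day as a block called 6 of these lists.

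All 10 precursor genes had positive fitted differences, and 9 passed adjusted over the list alone, all but Egfl7 (0.06 ± 0.12), against 0 over all genes. Fli1, an ETS factor of blood and endothelium, differed by 2.14 ± 0.54 (SE, 4 days; limma adjusted p = 0.416), and Kdr by 2.40 ± 0.69. All 12 streak genes and all 9 lateral plate genes were also positive, and 0 of either list passed adjusted over the list alone. The shared signs of these lists are in part built in, since a gene can pass the signal filter through Dox- arrays alone. Fli1, Isl1 and Tbx20 did so, with at most 5.9, 13.1 and 8.2 on any Dox+ array. Without the filter, 19 of 23 streak genes on D2.5 and 15 of 20 lateral plate genes on D3.5 were at least 2-fold higher, and 0 lower. Aplnr (2.82 ± 1.09) and Isl1 (1.91 ± 0.66) had large values. The extraembryonic endoderm list held Gata6 (1.84 ± 0.54) and the basement membrane collagen gene Col4a1 (1.18 ± 0.31), both also used in mesoderm. In it 0 members passed adjusted over the list alone. The trophoblast list held Cdx2 (1.78 ± 0.81), and 1 member, Krt8, passed adjusted over the list alone. Cdx2 is also on the streak list and Krt8 on the epithelial-mesenchymal list. The signal filter left out 9 of the 14 trophoblast genes with a probe set. Over all 14 the median was 0.20 on D1.5, 0.13 on D2.5 and 1.61 on D3.5. The signal target list held the BMP targets Id3 (1.44 ± 0.36) and Smad6 (1.58 ± 0.48) and, downward, the Nodal target Lefty1 (-1.40 ± 0.41), with 0 past.

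Among the lower lists, all 8 germline genes were negative, including Sycp3 (-1.16 ± 0.48), a meiotic chromosome axis gene. In general pluripotency, 12 of 15 genes were negative, with Utf1 at -1.53 ± 0.50 and Sox2 at -1.06 ± 0.41. The 2 members that passed adjusted over the list alone went opposite ways, Dppa5a at -1.31 ± 0.32 and Sall4 at 0.26 ± 0.06. The chromatin list held Dnmt3l (-0.89 ± 0.35) and the demethylase gene Kdm4c (-0.85 ± 0.27), whereas Ehmt2, which encodes the histone methyltransferase G9a, gave 0.07 ± 0.10. The hypoxia list had a median of -0.55 on D1.5, -0.53 on D2.5 and 0.15 on D3.5, with Adm, a hypoxia-inducible peptide gene, at -2.89 on D1.5. No member of the chromatin, germline or hypoxia lists passed adjusted over the list alone.

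The other lists did not pass: naive pluripotency (adjusted p = 0.125), DNA replication (0.152), primed epiblast (0.324), imprinted genes (0.324), mitosis, sterol synthesis and fibroblast genes (0.388 each), neural ectoderm (0.391), definitive endoderm (0.438), p53 and stress response (0.624) and interferon response (0.934). Definitive endoderm had a median of -0.06 and a mean of 0.29, so the measures differed in sign, as did those of the interferon list (0.07 and -0.02). Adjusted over the list alone, 2 imprinted genes (lowest adjusted p = 0.0258) and 2 DNA replication genes (0.0409) passed, and 0 members of the other 9 lists. Igf2, an imprinted growth factor gene, had the largest fitted difference among genes with 1 sign on all 4 days (3.19 ± 0.72, adjusted p = 0.416). Others upward included Ctla2a, Nrp1, Wnt5a, Dkk1, Cdh11, Klhl6, Lhx1 and Nkx1-2, and downward Abcc4 (-1.95 ± 0.63), Enpp3, Platr10, Myb, Dmrt1, Pla2g10 and Mkrn1, none past the threshold.

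With limma and the day as a block, 0 of 8716 genes passed a 5% false discovery rate, and 1026 had an unadjusted p under 0.05 (375 higher and 651 lower in Dox-), where chance alone gives 436. The difference of the arms was not alike from day to day, and this fit counts that change as spread.

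**Figure D3:**
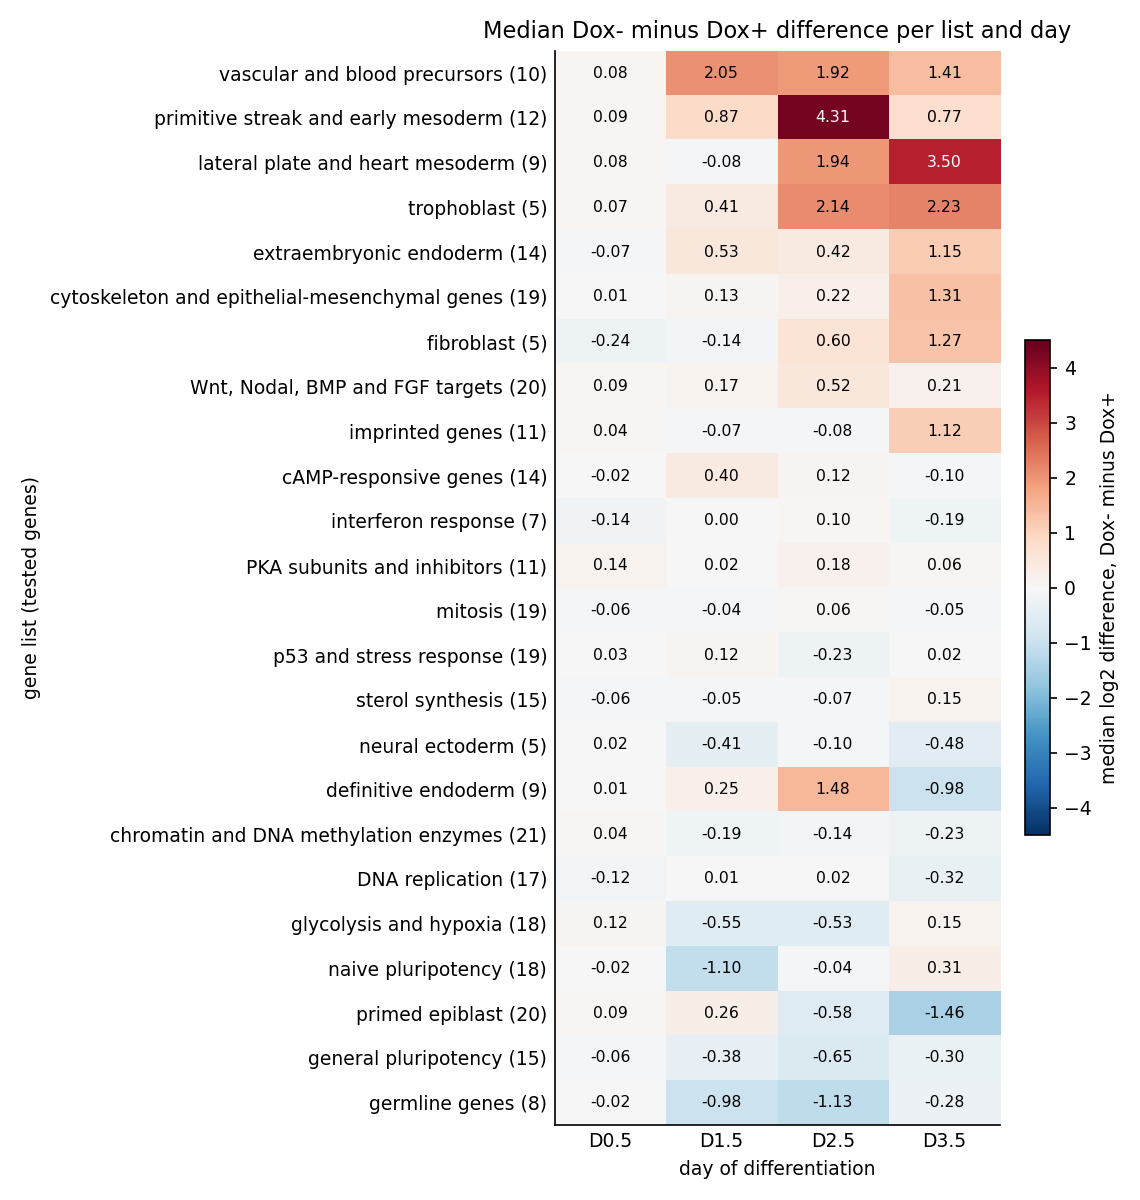
Median log2 difference between the Dox- and the Dox+ array (colour and printed value) of the tested genes of 24 gene lists (vertical axis, number of genes in brackets) on each day (horizontal axis). Precursor genes read 2.05 on D1.5, streak genes 4.31 on D2.5 and lateral plate genes 3.5 on D3.5.

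On D2.5 and D3.5 together, genes of lateral plate and heart mesoderm, the primitive streak and vascular and blood precursors were higher in Dox-, and primed epiblast and general pluripotency genes lower, by list tests of which none passed with an estimated correlation. This comparison was chosen after the values were seen: it tests 1 arm difference shared by D2.5 and D3.5, with the pairs of D0.5 and D1.5 as spread. It called 626 genes, 247 higher and 379 lower in Dox-, and 408 of them differed at least 2-fold. All 626 had the same sign on both days. The test itself all but requires this, since it counts a disagreement of the 2 days as spread, so the shared sign is no separate evidence. Wnt5a, a Wnt ligand of the streak region, was higher by 4.33 ± 0.21 (SE, 2 days; limma adjusted p = 0.000438). The ankyrin repeat gene Asb4 was higher by 4.13 ± 0.17 (adjusted p = 0.000224) and the caudal homeobox gene Cdx2 by 3.77 ± 0.25 (0.00135). Pou3f1 (Oct6), an epiblast and neural POU factor, was lower, at -3.40 ± 0.14 (0.000224), as was Abcc4, a transporter that exports cyclic AMP among other substrates, at -3.49 ± 0.24 (0.00135).

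Of the lateral plate and heart list, 7 of 9 tested genes were called higher and 0 lower, including the growth factor receptor gene Pdgfra (3.75 ± 0.58), Isl1 (3.36 ± 0.43) and the ligand gene Bmp4 (3.58 ± 0.55). The list's camera adjusted p = 2.98e-08, and adjusted p = 0.310 with an estimated correlation. Streak genes gave 4 higher of 12 (Nkx1-2 at 3.48 ± 0.31; adjusted p = 3.71e-06, and 0.554 with an estimated correlation). Precursor genes gave 2 of 10, Kdr (3.88 ± 0.58) and Nrp1 (4.03 ± 0.51), with adjusted p = 0.000234, and adjusted p = 0.554 with an estimated correlation. Trophoblast genes gave 3 of 5 (7.56e-05), with adjusted p = 0.310 with an estimated correlation, and extraembryonic endoderm genes 3 of 14 (0.0013), with adjusted p = 0.554. Over all 14 trophoblast genes with a probe set, dim ones included, the median was 0.13 on D2.5 and 1.61 on D3.5. The limit that the signal filter sets, given above, holds for the counts of higher genes here as well.

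Of general pluripotency, 5 of 15 genes were called lower and 0 higher, Utf1 by -2.74 ± 0.19 and Sox2 by -2.03 ± 0.19 (list adjusted p = 0.00121, and adjusted p = 0.408 with an estimated correlation). Of the primed epiblast list, 7 of 20 were lower and 3 higher, with Otx2 at -2.59 ± 0.58 and the de novo DNA methyltransferase genes Dnmt3a and Dnmt3b at -1.24 ± 0.22 and -1.05 ± 0.22 (0.0013, and adjusted p = 0.554 with an estimated correlation). Naive pluripotency genes did not pass (adjusted p = 0.715, and adjusted p = 0.883 with an estimated correlation), with a median of 0.04, 2 of 18 called higher, Tbx3 (3.48 ± 0.51) and Klf4 (1.28 ± 0.29), and 1 lower. Germline genes (2 of 8 lower, adjusted p = 0.0118) and chromatin genes (3 of 21 lower, adjusted p = 0.0379) also passed, both with adjusted p = 0.554 with an estimated correlation. Targets of Wnt, Nodal, BMP and FGF signals did not pass (3 of 20 higher and 2 lower, adjusted p = 0.147).

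Of the cytoskeleton and epithelial-mesenchymal list, 5 of 19 genes were called higher and 5 lower, and the test of the whole list pointed up (adjusted p = 0.025, and adjusted p = 0.408 with an estimated correlation). Epithelial and mesenchymal members were not tested apart. The epithelial adhesion genes Cdh1 (-1.99 ± 0.36), Epcam (-1.29 ± 0.23), Cldn4, Cldn7 and Ocln were lower in Dox-. Not all epithelial members went down: the keratin gene Krt8 was not called here and was higher in Dox- over the 4 days (1.17). The mesenchymal genes Cdh2 (1.93 ± 0.23), Vim (1.18 ± 0.15) and Fn1 (2.78 ± 0.22), and Zeb1 and Zeb2, repressors of epithelial genes, were higher. Of the cyclic AMP-responsive genes, Fos (2.08 ± 0.24) and Cited2 (1.70 ± 0.16) were higher and Kcnk1 (-1.66 ± 0.22) lower, and the list did not pass (adjusted p = 0.686), with a median of -0.08 although the test pointed up. Of the PKA, mitosis, sterol and p53 lists 0 genes were called. The 626 calls became 228 when D0.5 was left out and 328 when D3.5 was left out. Of those, 227 and 231 were among the 626.

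**Figure D4:**
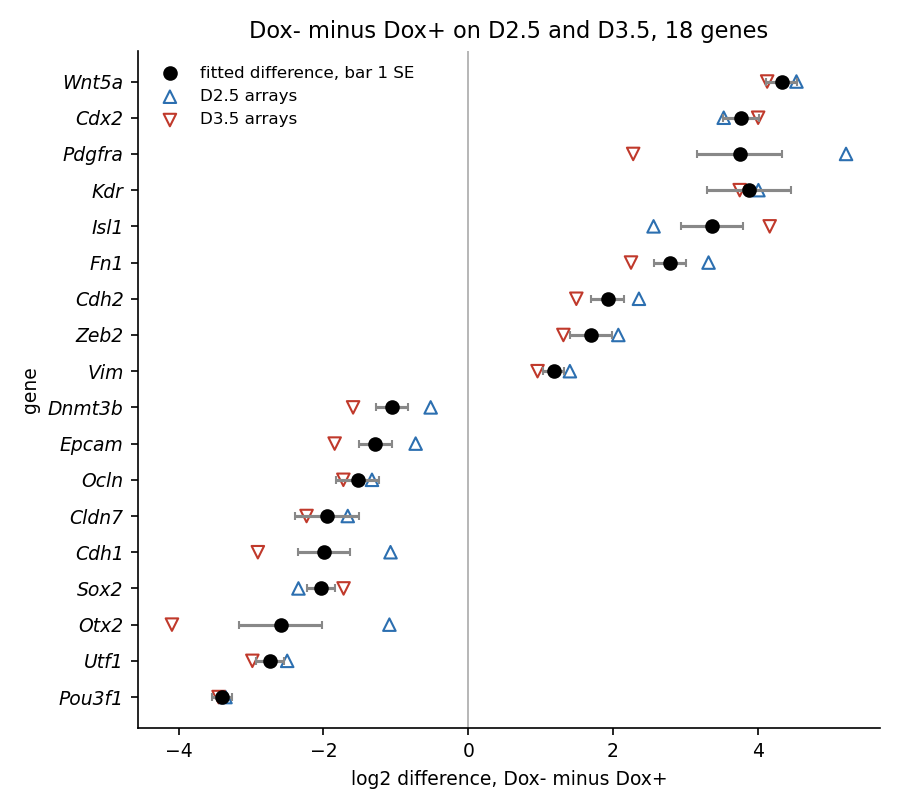
Fitted log2 difference, Dox- minus Dox+, of 18 named genes over D2.5 and D3.5 (filled circles, bars 1 SE), with the difference of the arrays of D2.5 (upward triangles) and of D3.5 (downward triangles). Wnt5a and Cdx2 lie above 3 on both days and Pou3f1 below -3, while Otx2 reads -1.09 on D2.5 and -4.09 on D3.5.

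Between D0.5 and D3.5, with both media together, cells lost naive pluripotency transcripts and gained sterol synthesis transcripts, by list tests that did not pass with an estimated correlation (adjusted p = 0.284 and 0.262). Zfp42 fell by 4.35 (SE 0.30, 2 arrays per day; limma adjusted p = 0.00292), and 14 of 18 naive genes fell, 15 adjusted over the list alone, while 0 rose. Dppa2 fell by 5.79 (adjusted p = 0.0032), Morc1 by 5.33 (0.0038) and Dnmt3l, a cofactor of DNA methylation, by 4.42 (0.00513). Upward, Krt8, a simple epithelial keratin, gained 4.86 ± 0.45 (0.0038), Tagln, an actin-binding gene of smooth muscle, 4.55 ± 0.33 (0.00292), and the Hippo pathway scaffold gene Amot 4.95 ± 0.66 (0.00738). Among called genes, Cyp26a1, which degrades retinoic acid, Cdh11, Krt18, Vldlr, Wls, Prickle1 and Fst completed the 10 largest rises. Mymx, Manba, Rpl39l, Ooep, Txnip, Nr0b1 and Tcf15 completed the 10 largest falls among called genes.

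Sterol synthesis genes rose together: 14 of 15 tested genes rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 9.33e-10, and adjusted p = 0.262 with an estimated correlation). Hmgcs1, the enzyme that makes HMG-CoA for this pathway, rose by 1.41 and Cyp51 by 1.49, and the list's medians between the media lay between -0.07 and 0.15 over the 4 days. Of the cytoskeleton and epithelial-mesenchymal list, 11 of 19 rose, the same number adjusted over the list alone (adjusted p = 0.000159, and adjusted p = 0.262 with an estimated correlation). Streak genes (3 of 12 rose, 12 adjusted over the list alone; adjusted p = 0.000292) and lateral plate genes (2 of 9, 7 over the list alone; 0.00479) were also higher, with adjusted p = 0.455 and adjusted p = 0.481 with an estimated correlation. Fibroblast genes gave 3 of 5 risen and 4 over the list alone (adjusted p = 0.00407, and 0.262 with an estimated correlation). Trophoblast genes gave 2 of 5 and imprinted genes 6 of 11, 2 and 8 adjusted over the list alone, where 1 imprinted gene fell (adjusted p = 0.00844 each, and adjusted p = 0.420 each with an estimated correlation).

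Cyclic AMP-responsive genes gave 4 of 14 risen, 5 adjusted over the list alone (adjusted p = 0.0172, and adjusted p = 0.420 with an estimated correlation), among them Id1 (2.37), Pde10a (1.96) and Irs2 (1.76), and glycolysis and hypoxia genes 3 of 18 risen and 1 fallen (0.0263, and adjusted p = 0.570 with an estimated correlation). Precursor genes gave 1 of 10, Flt1 (0.0263), and extraembryonic endoderm genes 3 of 14 risen and 1 fallen (0.0280), both with adjusted p = 0.536 with an estimated correlation. Interferon response genes gave 3 of 7, Irf1, B2m and H2-K1 (0.0471, and adjusted p = 0.317 with an estimated correlation). Adjusted over the list alone, these counts were 5 and 1, 0, 5 and 1, and 3.

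Downward, 10 of 15 general pluripotency genes fell, 12 adjusted over the list alone, where 2 rose (adjusted p = 4.78e-05), as did 7 of 8 germline genes (7.53e-05; 7 over the list alone), including Dazl, by 3.58. Chromatin genes (10 of 21; 0.000262), mitosis genes (7 of 19; 0.000292) and DNA replication genes (5 of 17 fallen and 1 risen; 0.00106) were also lower, with 10, 7 and 9 fallen adjusted over the list alone. These 5 lists had adjusted p between 0.262 and 0.421 with an estimated correlation, naive pluripotency (1.05e-09) an adjusted p = 0.284. The primed epiblast, definitive endoderm, neural ectoderm, PKA, p53 and signal target lists did not pass (adjusted p from 0.194 to 0.811). The primed epiblast list had a median of -0.11 and a mean of 0.10. Over all genes, 3 primed epiblast genes rose and 3 fell (4 and 3 adjusted over the list alone), 4 signal targets rose and 3 fell (6 and 3), 2 PKA genes rose and 1 fell (6 and 2), and 1 neural gene rose and 1 fell (1 and 1). No definitive endoderm gene passed either way, and 2 stress response genes fell (1 over the list alone).

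In all, 1917 genes differed between D3.5 and D0.5 (1027 higher and 890 lower), 1051 between D2.5 and D0.5 and 266 between D1.5 and D0.5. Without the D0.5 Dox- array 66 of the 1917 were left. The count was 894 without the D0.5 Dox+ array and 797 without the D3.5 Dox- array. The median of the tested genes was 0.10 higher on D3.5 than on D0.5, and after each array was centred on that median 830 genes were higher and 1158 lower (41.8% higher, against 53.6% as reported).

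Compared with undifferentiated cells, D0.5 cells of both media had lower naive pluripotency and higher primed epiblast transcripts. Socs3, a feedback inhibitor that leukemia inhibitory factor induces, read 1824 in undifferentiated cells and 158 and 149 on the D0.5 arrays, a mean log2 difference of -3.44. Fos differed by -2.49 and Trh by -2.43. Upward, Lef1 differed by 2.83, Pou3f1 by 2.78 and Otx2 by 2.61. Naive pluripotency genes had a median difference of -0.95, below all of 10000 random lists matched on expression, and primed epiblast genes 0.97, above all of them. Glycolysis and hypoxia genes had a median of 0.66, also above all of them. Extraembryonic endoderm genes fell as well, with a median of -0.69, below all of the random lists. By D3.5 the mean differences were 5.61 for Aplnr, 5.29 for Fndc3c1, -6.32 for Morc1 and -5.40 for Inhbb. At least 2-fold from undifferentiated cells were 238 genes on the Dox+ array of D0.5 and 250 on the Dox- array, and 1522 and 1883 on D3.5. Undifferentiated cells are 1 array, so these differences carry no test.

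Whether the arm difference changed steadily with the day was tested per gene, and limma called 0 of 8716 genes, with 736 at an unadjusted p under 0.05. The smallest p-values belonged to Igfbp4, an insulin-like growth factor binding protein (1.01 ± 0.11 per day, adjusted p = 0.342), and to Ccne1, cyclin E1 (-0.61 ± 0.08), and Pgap1 (-0.82 ± 0.11), both at 0.367. Igfbp4 read 45.7, 140.1, 246 and 661 on the Dox- arrays and 54.0, 56.9, 54.2 and 73.2 on the Dox+ arrays.

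The Dox- array of D1.5 lay nearer to the Dox+ arrays of D2.5 and D3.5 than to that of its own day. Its root mean square difference over the 8716 genes was 0.400 to the D1.5 Dox+ array, 0.303 to D2.5 and 0.372 to D3.5. The D2.5 Dox- array was nearest to the D3.5 Dox+ array, at 0.419, against 0.624 to that of its own day. On D0.5 the arms were 0.204 apart.

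**Figure D5:**
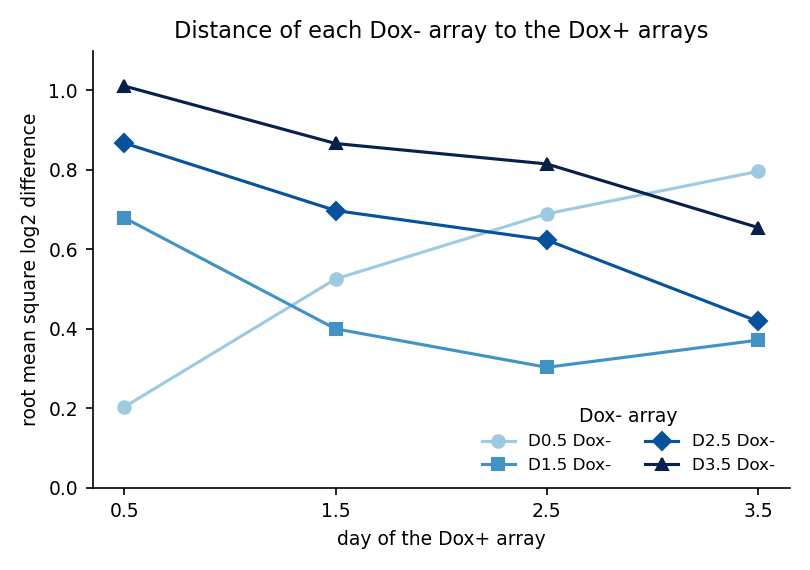
Root mean square log2 difference over 8716 genes (vertical axis) between each Dox- array (lines) and the Dox+ arrays of D0.5 to D3.5 (horizontal axis), 1 array per point. The lowest point of the D1.5 Dox- line is at D2.5 (0.303) and that of the D2.5 Dox- line at D3.5 (0.419).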

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

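The tests of gene lists for a steady change of the Dox- minus Dox+ difference with the day, and the counts over other splits of the arrays, were chosen only after values were seen.

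For 11 of the 24 lists the difference between the media changed with the day by a test of that change itself (camera on the product of medium and day). Lateral plate and heart genes had a median change of 1.31 per day toward Dox- (adjusted p = 1.46e-06, and adjusted p = 0.308 with an estimated correlation), trophoblast genes 0.65 (0.00101; 0.175) and extraembryonic endoderm genes 0.37 (0.00101; 0.175). Vascular and blood precursors gained 0.36 per day (0.00374; 0.514), epithelial-mesenchymal genes 0.37 (0.0370; 0.267), imprinted genes 0.25 (0.0370; 0.526), primitive streak genes 0.52 (0.0432; 0.736) and fibroblast genes 0.46 (0.0432; 0.305). In the other direction, primed epiblast genes changed by -0.53 per day (0.00040; 0.492), general pluripotency genes by -0.15 (0.00162; 0.175) and chromatin enzymes by -0.07 (0.0292; 0.267). None of the 11 passed with an estimated correlation. Without D0.5 the test called 9 lists, of which 4 were among the 11, so the call rests in part on the day on which the media hardly differed.

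Other splits of the 8 differentiating arrays into 4 and 4 were fitted in the same way. For the lists that differed between the media the real count was 11, the highest other was 11, from the split with the D0.5 arrays exchanged between media, and 2 of 32 splits gave as many, so chance was not excluded. Of the 8 splits that part the arrays of every day, as the real one does, 2 gave as many, the real one included, and the highest other was 11. The remaining splits put both arrays of at least 1 day on the same side. For the lists that changed with the day the real count was 11 and the highest other 14, with 8 of 35 splits as large, so chance was not excluded there either. Among the 8 splits that part every day 4 were as large, and the highest other was 12. With 8 splits no share under 0.05 can be had. By limma, the count of genes that differed between the media was 0, with 1026 at an unadjusted p under 0.05. No split can give fewer than 0, so a comparison with the 32 splits says nothing on chance. The highest other gave 626, which came from the 2 splits that keep the media of D2.5 and D3.5 apart and pool both arrays of D0.5 and both of D1.5 on opposite sides. With the day as a block, these 2 splits are the same fit as that of D2.5 and D3.5 given above. Their 626 genes therefore restate the difference between the media shared by D2.5 and D3.5 and are no separate evidence for it. For single genes that changed with the day the real count was 0, with 736 at an unadjusted p under 0.05, and for the same reason the 35 splits say nothing on chance. The highest other, 682, came from 1 of the same splits.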

How the results depend on the processing

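The alternatives were fixed before the data were examined, except those of the lists that changed with the day, of the fit of D2.5 and D3.5, of the genes outside the Dox+ course and of the list medians, which were chosen after the values were seen. Limma called 0 genes between the media under every alternative of that fit (as reported, 1026 had an unadjusted p under 0.05), and 626 in the fit of D2.5 and D3.5, which takes the difference of the earlier days as spread. Lists that differed between the media numbered 9 to 13 over the scalings, filters, pseudocounts and days left out, 6 without the day as a block and 0 with an estimated correlation. Those that differed between D3.5 and D0.5 were 13 to 18, and 0 with an estimated correlation. Lists that changed with the day were 7 with a pseudocount of 1, 0 with an estimated correlation and 9 to 12 otherwise. The cause was not tested for these, nor for the other changes given here.

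Counts of genes at least 2-fold apart depended on the pseudocount. With a pseudocount of 1 they were 77 on D0.5 and 425 on D1.5, and against undifferentiated cells 469 (D0.5 Dox+) and 506 (D0.5 Dox-). With a pseudocount of 64 they were 1, 82, 343 and 414 on the 4 days. On D0.5 they were 20 with no filter, 6 with a filter of 100 and 2 with the mean of all probe sets, which gave 153 on D1.5. Without the filter the list medians moved by more than the SD of all D0.5 differences for 1, 7, 7 and 7 of 24 lists on the 4 days, that of definitive endoderm on D3.5 from -0.98 to 0.03. Genes above the Dox+ course on D1.5 were 32 and 7 with pseudocounts of 1 and 64. Leaving out 1 array gave 66 (without D0.5 Dox-) to 1559 genes between D3.5 and D0.5, with 894 without D0.5 Dox+ and 797 without D3.5 Dox-; other settings gave 1469 to 1988. In the fit of D2.5 and D3.5, leaving out 1 day gave 228 (without D0.5) to 791 genes, with 328 without D3.5, and other settings 473 to 655.

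Among the named genes of the fits over all 8 arrays and the lists compared between the media, no result past its threshold changed direction. Direction was not followed for the lists compared between days, the lists that changed with the day or the genes of the fit of D2.5 and D3.5. Of the values of named genes under the alternatives, 860 of the comparison of days stayed on their side of the threshold, 139 lost it, 19 gained it and 1, that of Otx2 without D3.5 Dox-, came to 0.01. Of the values between the media 1168 stayed and 4, none past the threshold, changed sign without D3.5: those of Prkaca (0.11), Nanog (0.04), Fgf5 (0.09) and H2-K1 (0.07). Signals near background, which lie below the pseudocount of 16, limit what can be said of dim genes such as Fli1 and Tbx20 in Dox+ cells.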

Other observations

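The tests of distances between the media, of genes above the Dox+ course and of lysosomal genes as a group were chosen only after the values were seen. The lists of lysosomal genes and of mature endothelial and blood markers were written then too. The change of lysosomal genes along the Dox+ arrays from D0.5 to D2.5 was the exception.

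Hypoxia-inducible genes were lower in Dox- on D1.5 and D2.5 but not on D3.5. The list's median lay below all of 10000 matched random lists on both days, at -0.55 and -0.53. On D3.5 it went the other way, at 0.15 and the 99.09 percentile, with 5 of 18 genes at least 2-fold higher and 1 lower. Pdk1, which holds pyruvate back from the mitochondria, differed by -1.04 on D1.5 and -1.90 on D2.5, and Bnip3, a mitophagy receptor, by -0.82 and -1.60. Outside this list, Ddit4, which inhibits mTORC1, differed by -1.13 and -2.14 and the repressor Bhlhe40 by -1.99 and -3.17; these are single arrays with no test per day.

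On D3.5, 6 of 11 tested imprinted genes were at least 2-fold higher and 1 at least 2-fold lower in Dox-, with a median of 1.12. Over all 18 genes of the list with a probe set the median was 0.67. Other lists lay higher on that day, among them lateral plate and heart genes at 3.5. The imprinted list did not pass in the comparison of media (camera adjusted p = 0.324). Igf2 differed by 5.54 on that day, Sgce, a sarcoglycan, by 2.25 and Peg3, a zinc finger gene, by 1.27. The 8 tested germline genes had medians of -0.98 on D1.5 and -1.13 on D2.5, and all 17 of the list -0.22 and -0.48. Among interferon response genes, Ifitm1, also a gene of early mesoderm, was called higher on D2.5 and D3.5 together (2.49) and Bst2 lower (-2.17).

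The Dox- array of D1.5 lay nearest to later Dox+ arrays, at day 2.82 of a course drawn through the Dox+ arrays. Scaling that depends on intensity is argued against, since the array still lay at day 2.82 after quantile normalization, which moved its values by a root mean square of 0.0136. A candidate explanation is that Dox- cells ran ahead along the Dox+ course: the D1.5 difference correlated across genes, which are not independent replicates, with the change of the Dox+ arrays from D0.5 to D2.5 at r = 0.335 (rho 0.212), and the D2.5 difference with their change from D1.5 to D3.5 at r = 0.525 (rho 0.436), from separate arrays. With the change of the Dox+ arrays from D1.5 to D2.5, the D0.5 difference correlated at r = 0.0621 (rho 0.0671). The D3.5 difference correlated with that change at r = -0.122 (rho -0.0581). For D3.5 this decides nothing on running ahead. The Dox- array of D3.5 lay at the end of the Dox+ course, and the change after D3.5 was not measured. At least 2-fold outside all Dox+ and undifferentiated arrays, 109 genes lay above and 43 below on the Dox- array of D2.5, and 234 and 149 on that of D3.5. An exchange with a later Dox+ array stays open too. The summed root mean square distance to the Dox+ arrays of D1.5 and D3.5 was 0.772 for the D1.5 Dox- array and 0.675 for the D2.5 Dox+ array, and the distance to the D2.5 Dox+ array was 0.303 for the D1.5 Dox- array and 0.356 for the D3.5 Dox+ array, and single arrays give no spread to judge these by. Doxycycline itself stays open as a cause, untested, as no cells without the kinase construct were analysed here.

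On the Dox- array of D1.5, 21 genes lay at least 2-fold above every Dox+ and undifferentiated array and 0 below (32 and 7 outside with pseudocounts of 1 and 64), and 7 of the 21 were among the 10 tested precursor genes, which had already been seen to be higher on this array, so no test was made. They included Etv2, Tal1, Fli1, Lmo2, Gata2, the embryonic globin gene Hbb-bh1, Sox7, Sox17 and Sox18, and 18 of the 21 were still above on D2.5 and 12 on D3.5. An earlier but otherwise like copy of the Dox+ course, with a peak missed by sampling once a day, is argued against. On the D2.5 Dox- array, which lay nearest to the end of that course, the same genes were above the highest Dox+ or undifferentiated array by a median of 1.52 (bounds 1.24 to 2.5, n = 21 genes), so the D3.5 Dox+ array would have had to show them. A Dox+ array of D1.5 or D2.5 lay outside the others by at most 8 genes. Whether mature endothelial or blood cells were present stays open. Their markers had a median difference of 0.20 (bounds -0.17 to 0.95, n = 12 genes, of which 9 were also written on the precursor list), but only 1 of the 12, Egfl7, passed the signal filter, and genes near background exclude nothing. Esam read 48.6 against 3.6 in Dox+ on D1.5, Cdh5 23.1 against 0.7 and Eng 51.5 against 19, while Emcn read 5.1 against 6.3 and Hba-a1 0.2 against 5.3.

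Lysosomal genes were lower in Dox-, noticed from Hexa (-0.61), Fuca2 (-0.65), Dpp7 (-0.78), Atp6v0b (-0.55) and Atp6v1d (-0.56), none past the threshold. Of 40 other lysosomal genes 33 were lower, with a median of -0.17 (camera p = 1.84e-05, and p = 0.133 with an estimated correlation), so a shift of the group may be present but rests on the preset correlation. On D1.5, whether Dox- cells running ahead were the whole cause stays open. The distance of the D1.5 Dox- array from the Dox+ course, at its own place on it, had a median of -0.127 over the 40 genes. Its bounds, -0.21 to -0.04, take the genes as independent, and the median difference between the media was -0.15. The median of all tested genes was also lower on this array, at 7.64, against 7.67 and 7.70 on the Dox+ arrays of D2.5 and D3.5. These bounds take no account of that offset. Along the Dox+ arrays these genes changed by 0.00127 from D1.5 to D2.5 and by -0.07 from D1.5 to D3.5. Their change of 0.544 from D0.5 to D2.5 (bounds 0.316 to 0.692) decides nothing, since the rise lay before D1.5 (0.519 from D0.5 to D1.5). On D2.5 running ahead stays open too. The distance from the D3.5 Dox+ array had a median of -0.205 (bounds -0.28 to -0.10), but the Dox- array was at the end of the course, and the change after D3.5 was not measured. Fnip1, a partner of folliculin at the lysosome, had the smallest p of all genes between the media (-0.89 ± 0.15; limma adjusted p = 0.416), lower on 4 of 4 days, and Flcn itself gave -0.60. These genes were named after their values were seen.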
